A study of Larimichthys crocea with 2 samples.

How the data were processed

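Total RNA was extracted with Trizol from muscle frozen in liquid nitrogen and made into small RNA libraries by standard Illumina methods, per the labels' protocols. The 2 libraries were assigned to the fed control and the fasted group from the labels. The adapter trimming, aligner, miRNA reference, its version and the genome build are not given in the sources used here.

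The authors deposited, for each library, read counts per miRNA name with 1 sequence for each name. Names carry no species prefix, and many overlap in sequence and hold nearly the same reads, so the counts summed over names (16939176 fed and 26028115 fasted) were 1.50 and 2.21 times the library totals. The authors also deposited a table of 609 names with counts, RPM (reads scaled to the library total), log2 fold changes and p-values for the 2 libraries. Its counts were equal to those of the per-library lists for all 609 names. In the authors' deposited table, 0 reads were written as 0.01 RPM, the smallest absolute log2 fold change was 1.02 and the largest p-value was 0.0339, with 269 names higher and 340 lower in the fasted library. The test behind the authors' p-values is not given in the sources used here, and with 1 library per group they are not used. The deposited target predictions give an alignment score and an energy for each site, and a further deposited file of each library gives a context+ score for each seed site, which was not used here.

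Library totals were taken from the deposited counts divided by the authors' RPM, and the 464 names with reads in the fed library and the 429 in the fasted library gave a total within 0.0262% and 0.0503% of the one used. The scaling fixed before the data were examined was the sum over all names. It was replaced as the main scaling once the overlapping names had been seen, because that sum counts the same reads several times, and it is given as an alternative. A log2 ratio is fasted over fed control with a pseudocount of 1 read added to each count, and ratios in fold are without it. Intervals of ratios are exact conditional binomial intervals at 95%, shares have Wilson intervals, and a count of 0 was given a floor of 3 reads per library, which is 0.266 RPM in the fed and 0.255 RPM in the fasted library. Differences between 0 and a few reads were therefore not detectable.

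A name was counted as higher or lower where it had at least 50 reads in 1 library, a ratio of at least 2 and an interval that excluded 1. No test across names was run and no p-value was computed. The median of each of 11 fixed lists was set against 10000 random lists of the same size matched on deciles of mean expression, among 1077 names with at least 10 summed reads. This percentile describes these libraries, and it is too precise where names share reads. The named miRNAs were the 10 highest and 10 lowest log2 ratios among names meeting the size rule, the 10 most abundant names and up to 4 most abundant members of each list. This rule, the lists and the size rule were fixed before the data were examined.

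After the data were examined, each name was classed by its sequences in the 2 libraries as identical (507 names), overlapping by a run of at least 16 bases (175), different (129) or listed in 1 library alone (452 fed, 530 fasted). Entries with a shared run of 16 bases were merged into 1562 sequence groups, each with the highest count per library, and 471 groups had at least 50 reads. Predicted targets were counted as distinct transcripts per name. Of 29064 transcripts in the fed library's file, 12474 matched a gene of the L_crocea_2.0 annotation once accession versions were ignored, and 9710 of these had a symbol other than a locus number, so list genes outside these were not assessed.

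The size rule was tested on simulated data in which 200 of 1793 names were changed between the fasted and fed library. Names with enough reads were recovered in 100% of cases at 3-fold (17 names), 6-fold (22) and 12-fold (26), in 0% at 1.5-fold (19), and 0% of 546 unchanged names were counted. Both simulated libraries were drawn with Poisson counting noise alone from shared levels. Differences between fish, library preparations or listed sequences were not simulated. The values therefore check the working of the rule and give no rate of false calls for real libraries. Alternatives were median centring, TMM factors from edgeR 4.0.16 in R 4.3.3, totals without miR-10b-5p, other pseudocounts (0.5 and 5 reads), read minimums (10, 200 and none) and ratios (1.5 and 4). The rest was computed in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and networkx 3.6.1, and figures were drawn with matplotlib 3.10.9.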

Results

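Small RNA was sequenced from skeletal muscle of the large yellow croaker, a marine food fish, in 2 libraries. The fed control library came from fish on a normal diet (0 days of fasting) and the fasted library from fish without food for 21 days. Each group had 1 library, so no difference below has a replicate check, and each describes these libraries rather than the conditions. The library totals were 11258312 reads (fed) and 11772639 reads (fasted). The fed library listed 1263 miRNA names and the fasted library 1341, with 1793 names in either and 811 in both. All intervals are 95% and cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

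The first question was which miRNAs made up the muscle libraries. miR-10b-5p, a miRNA encoded within the Hox gene clusters, was the most abundant name in each. It held 32.0% of the fed library (Wilson interval 32.0 to 32.0) and 58.6% of the fasted library (58.5 to 58.6), a fasted over fed ratio of 1.83. The names miR-10b and miR-10c-5p were close to it, with log2 ratios of 0.86 and 0.84, and their sequences overlapped that of miR-10b-5p, so the same reads were listed under several names. After names with overlapping sequences were merged, with each group at the highest count of its names, the 10 most abundant sequence groups held 46.2% (46.2 to 46.2) of the fed and 74.2% (74.2 to 74.3) of the fasted library. On the same count the sequence groups other than that of miR-10b-5p together held 24.9% and 22.9%. The counts left 43.1% and 18.5% of reads uncovered, which is not a measured share of unlisted reads, since reads of a group's other names can fall among them. The share of miR-10b-5p depends on the denominator. It was 56.2% (fed) and 71.8% (fasted) of the sum over sequence groups, and 21.3% and 26.5% of the sum over all names.

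Other abundant names lay closer to each other in the libraries. let-7-5p, of the family that regulates developmental timing, stood at 19988 RPM (reads scaled to the library total) in the fed and 32626 in the fasted library, a ratio of 1.63 (1.62 to 1.64). miR-181a had a log2 ratio of -0.51 and miR-181a-5p of -0.53. miR-143-3p and miR-143, known from smooth muscle, had -0.20 and -0.19. miR-21-5p had -0.03. The muscle-specific miR-133a-3p stood at 14423 and 9312 RPM (log2 -0.63), which became 0.08 when miR-10b-5p was left out of the library totals. The log2 ratios of miR-181a, miR-181a-5p, miR-143-3p, miR-143 and miR-21-5p also turned positive then, to 0.52 for miR-143-3p. Those of miR-143-3p, miR-143 and miR-21-5p turned positive with median centring as well. let-7e (3.10-fold, 3.08 to 3.12) and miR-10 (743550 reads in the fed and 1345 in the fasted library) were also among the 10 most abundant, but each of these names stood for different sequences in the 2 libraries, with no shared run of 16 bases. The more abundant sequence of each lay in a sequence group with a log2 ratio of 0.71 (let-7e) or 0.87 (miR-10), and neither group met the size rule described next.

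The comparison of the fasted with the fed library was made by a fixed rule of size: at least 50 reads in 1 library, a ratio of at least 2 and a counting interval that excludes 1. Of 682 names with at least 50 reads, 152 were higher and 218 lower in the fasted library, and 312 met neither side. Higher names made up 41.1% of those meeting the rule. This split was 57.8% when miR-10b-5p was left out of the totals and 27.8% when the sum over all names was the total. Those scalings moved every log2 ratio by 0.71 and -0.56, and median centring and TMM moved it by 0.20 and 0.16. The median log2 ratio of names with at least 50 reads in both libraries was -0.20.

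The extremes by name were read in 1 library alone or nearly so. The 10 names with the highest ratios had 0 reads in the fed library: miR-6585-5p (232007 fasted reads, at least 73957-fold higher against a floor of 3 reads per library), miR-4967-5p, miR-4175-3p, miR-7235-5p, miR-1337, miR-3473b, miR-103b, miR-1956-3p, miR-2885 and miR-6608-5p, the last at least 184-fold higher. Among the 10 lowest, miR-150-3p (55126 fed reads, at least 19215-fold lower), miR-3966, miR-5360-3p, miR-4508, miR-2371, miR-4034-5p, miR-34-3p, miR-3896-5p and miR-1421g-5p had 0 reads in the fasted library, and miR-8528a had 50372 fed and 2 fasted reads. In sequence groups, miR-1956-3p and miR-2885 joined miR-8528a in a group with a log2 ratio of -1.28, and miR-4175-3p lay in one with -1.17. The group of miR-4508 had 11918 fed and 1610 fasted reads, a log2 ratio of -2.95. miR-103b joined the group of miR-107b, which had a log2 ratio of 0.34.

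**Figure D1:**
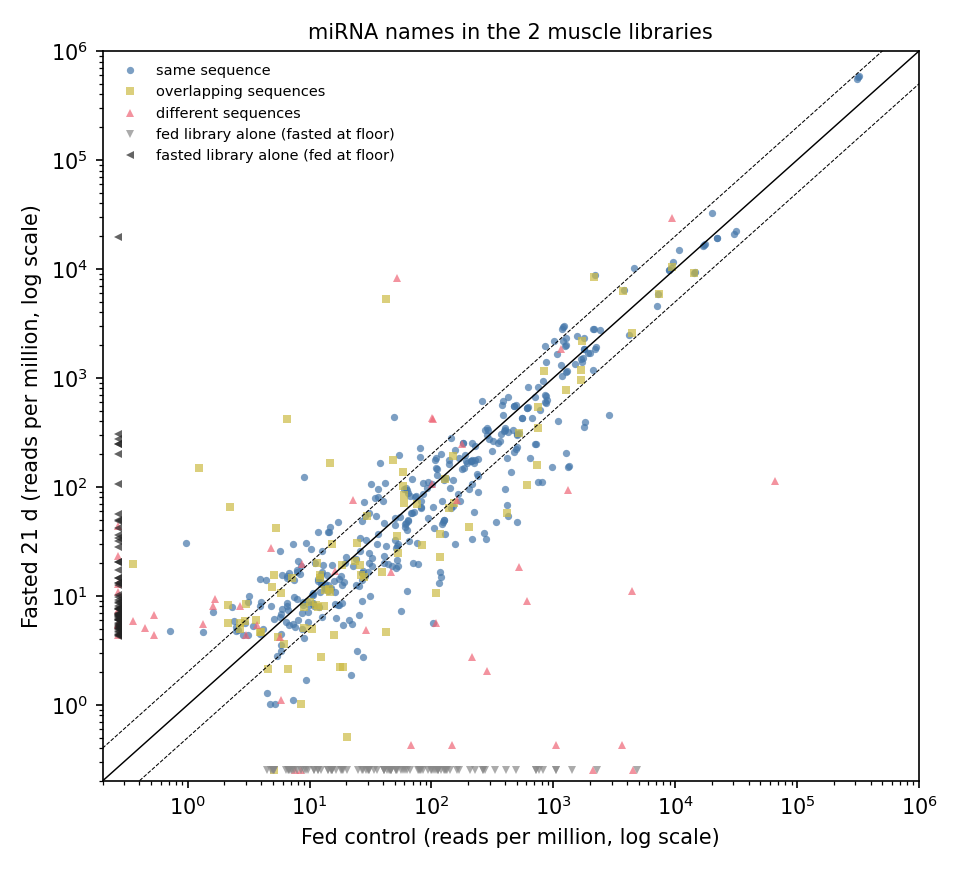
RPM of each miRNA name with at least 50 reads in 1 library, fed control on the x axis and fasted on the y axis (both log scales), 1 point per name, with values below the floor of 3 reads drawn at the floor. The solid line marks equal values and the dashed lines a ratio of 2. Of 385 names of the same sequence, 258 met neither side of the size rule, and the 159 names read in 1 library alone lie along the axes.

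Names with the same sequence in both libraries gave smaller ratios. Of 385 such names with at least 50 reads, 51 were higher, 76 lower and 258 neither. The highest of these, chosen after the values were seen, included miR-125a-3p (11 and 361 reads, 31.4-fold higher, 17.3 to 63.4), miR-6626-5p (13.7-fold, 11.2 to 16.9), miR-4012-3p (8.85-fold, 8.11 to 9.68), lin-4-5p (4.40-fold, 3.96 to 4.90) and miR-10d (4.0-fold, 3.95 to 4.06). A sequence that differs by 1 base from that of miR-125a-3p, listed as miR-125b-1-3p, had 1160 fed and 0 fasted reads. The rule for overlapping sequences did not merge these names. Whether reads of the same RNA were listed under different names in the libraries was not tested, so the direction of miR-125a-3p was not settled. The sequence of miR-10d overlaps that of miR-10b-5p, and their group, with a log2 ratio of 0.87, did not meet the size rule. The lowest included miR-2899 (18.2-fold lower, 14.2 to 23.7, but log2 -1.81 for its sequence group of 1458 and 434 reads), miR-7930-3p (10.4-fold lower, 9.54 to 11.4), miR-7446-3p (8.79-fold lower, 8.37 to 9.24), miR-542-3p (8.76-fold lower, 7.42 to 10.4) and miR-84a (8.67-fold lower, 8.26 to 9.11). An identical sequence in both libraries does not show that a name is a miRNA. The listed sequences of the lowest names given here are 18 to 20 bases long. Those of miR-6087, miR-6729-5p and miR-2966, also among the 10 lowest of identical sequence, have 21, 22 and 25 bases. Those of miR-6626-5p, miR-4012-3p and lin-4-5p are 18 or 19 bases long. Others among the 10 highest are longer, with 22 bases for miR-125a-3p, miR-10d, miR-4667-5p and miR-29c-5p. Whether any of these sequences are fragments of other RNAs was not tested.

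The muscle miRNAs (myomiRs: miR-1, miR-133, miR-206, miR-208, miR-499) had a median log2 ratio of -0.63 over 24 names, at the 10.6th percentile of random lists. Of 18 members with at least 50 reads, 1 was higher, 5 lower and 12 neither. Among the 17 members of identical sequence, 0 were higher and 5 lower. The abundant members were all miR-133: miR-133-3p, miR-133b and miR-133c-3p had log2 ratios of -0.63, -0.62 and -0.64. The mean of the list was 0.03, of the other sign than its median. Over the 17 members of identical sequence the median was -0.87, at the 0.47th percentile, but many of these share reads, and the 8 sequence groups of the list had a median of -0.81 at the 42.1th percentile. With miR-10b-5p out of the totals the median of the 24 names was 0.080.

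The family of miR-10, miR-99, miR-100 and miR-125 was the list that stood apart. Its 36 names had a median log2 ratio of 0.52, at the 99.95th percentile of random lists (central 95% -0.56 to 0.22). Of 33 members with at least 50 reads, 9 were higher, 3 lower and 21 neither. The higher members include miR-125a-3p, with the limit given above. Several members share reads, so the percentile treats as separate what was partly counted together. Among the 24 members of identical sequence, 3 were higher and 2 lower. With sequence groups in place of names, the median of 19 groups was 0.19 at the 93.8th percentile, inside the central 95%. By the size rule 2 of these groups were higher and 3 lower, so the excess of higher names was not kept once names were merged. With the sum over all names as the total, the median of the 36 names was -0.037.

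The let-7 family had a median log2 ratio of 0.12 over 32 names (79.1th percentile; mean -0.22), with 3 members higher, 4 lower and 15 neither. The name let-7 was 2.19-fold higher (2.17 to 2.22), but its sequence group of 15 names, with a log2 ratio of 0.71, did not meet the size rule. let-7k-5p had a log2 ratio of 0.29. The median of the family was -0.32 over 17 sequence groups and -0.43 with the sum over all names as the total. The miR-17-92 and paralogous clusters, linked to cell proliferation, had a median of 0.22 over 33 names (89.7th percentile), with 1 higher, 0 lower and 23 neither, and this median was -0.34 with the sum over all names as the total. Among them miR-25-3p had a log2 ratio of 0.87, miR-92a-3p of 0.19, miR-92c of 0.05 and miR-92a of 0.04. Lists were matched by name alone, and the 1 higher name, miR-17-3p, was read in the fasted library alone (149 reads). Its listed sequence resembles that of miR-143-3p. Of the 24 members of identical sequence in these clusters, 0 were higher and 0 lower.

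The list from the literature on muscle wasting and fasting had a median of -0.18 over 74 names (73.9th percentile), with 8 higher, 16 lower and 37 neither. This median turned to 0.028 with median centring and was -0.018 with TMM. The miR-30 family had a median of -0.51 over 18 names (13.4th percentile), with 1 higher, 5 lower and 12 neither. Among its 16 names of identical sequence, 0 were higher and 5 lower. Its abundant members miR-30b-3p, miR-30c-3p, miR-30a-3p and miR-30d-5p had log2 ratios of -0.50, -0.57, -0.52 and -0.45. The lipid and glucose metabolism list had a median of -0.35 over 29 names (42.3th percentile), with 2 higher, 3 lower and 15 neither. Among its 19 names of identical sequence, 0 were higher and 0 lower. Its member miR-375, known from pancreatic islets, had a log2 ratio of 0.73.

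Lists of miRNAs typical of other cell types lay inside the range of random lists. Blood cell miRNAs had a median of -0.46 over 32 names (29.0th percentile), with 1 higher, 5 lower and 14 neither, and miR-16b, miR-16 and miR-16-5p had log2 ratios of -0.93, 0.36 and -0.37, but form 1 sequence group with -0.33. The lower blood cell names include miR-150-3p, read in the fed library alone. Its listed sequence resembles that of miR-2014-5p (3081 fed and 0 fasted reads). Since lists were matched by name alone, whether it is a blood cell miRNA was not tested. The name miR-150 had 41 fed and 71 fasted reads (log2 0.71). Of the 15 blood cell names of identical sequence, 0 were higher and 2 lower. Endothelial and connective tissue miRNAs had -0.25 over 31 names (71.6th percentile), with 1 higher, 3 lower and 24 neither. Among their 24 names of identical sequence, 0 were higher and 0 lower. Their most abundant members miR-199b-3p, miR-199a-3p, miR-199-3p and miR-199b ranged from -0.25 to -0.17. Neural miRNAs had -0.23 over 22 names (45.2th percentile; mean 0.28; 0.045 over 11 sequence groups), with 2 higher, 0 lower and 13 neither, and miR-9-5p, miR-9a-5p, miR-128 and miR-128-3p had 0.80, 0.67, -0.33 and -0.36. Among the 15 neural names of identical sequence, 0 were higher and 0 lower. Epithelial miRNAs had -0.18 over 27 names (62.3th percentile), with 4 higher, 1 lower and 8 neither. This median turned to 0.37 over the 15 names with at least 50 summed reads (94.8th percentile) and to 0.020 with median centring. Of these, miR-192 was lower (log2 -1.52), while miR-203b-3p, miR-203-3p and miR-205-5p had log2 ratios of 0.48, 0.49 and -0.42. When miR-10b-5p was left out of the totals, miR-192 no longer reached a ratio of 2 and miR-205-5p turned positive. The log2 ratios of miR-203b-3p and miR-203-3p turned negative with the sum over all names as the total. With miR-10b-5p out of the totals, 8 of the 11 list medians had the other sign, namely each of those given above as negative. Setting members with 0 reads at their bound left each of the 11 list medians at the value given. This could hardly have been otherwise, since such members lie far from the median either way.

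**Figure D2:**
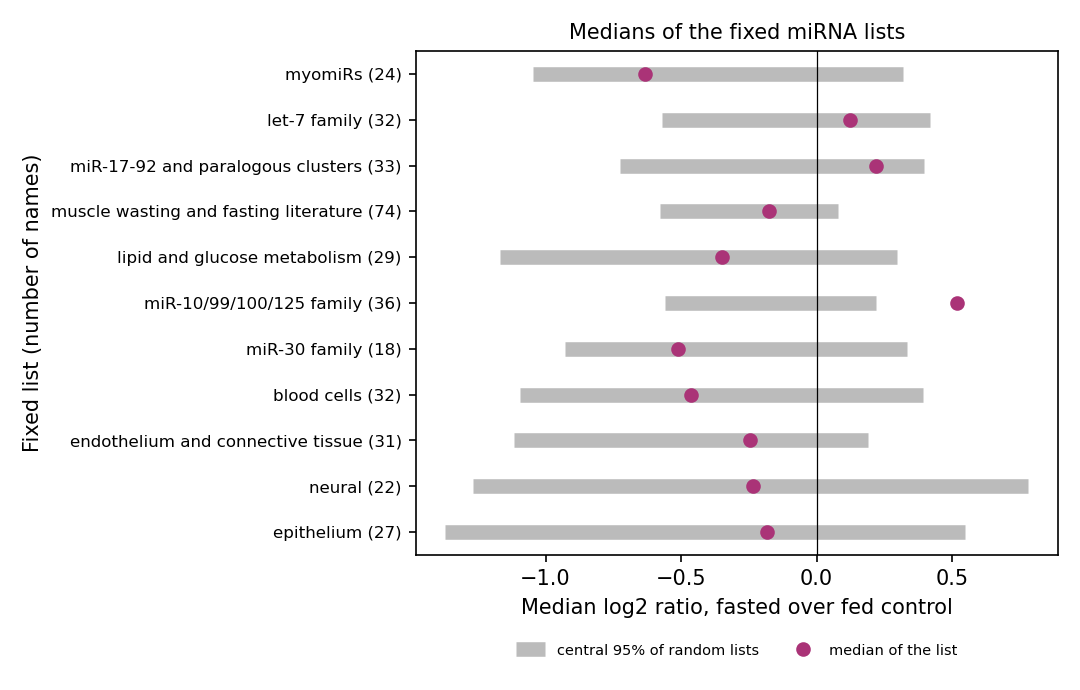
Median log2 ratio (fasted over fed control) of each fixed miRNA list, with the number of names beside the list; the points are medians and the grey bars the central 95% of 10000 random lists matched on mean expression. The family of miR-10, miR-99, miR-100 and miR-125, at 0.52, lies outside its bar, and the other 10 medians lie inside theirs; with the sum over all names as the total its median was -0.037.

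The authors' predicted targets were described for the 10 most abundant names. Their median number of target transcripts was 722 in each library, and miR-10b-5p had 622, let-7-5p 1281. Of 8044 genes with a symbol and a predicted site, 1089 (13.5%) had a site for at least 1 of these 10 names. In the fixed gene lists these were 2 of 11 protein breakdown genes, 1 of 8 growth signalling genes, 0 of 5 autophagy genes, 1 of 10 fuel use genes and 0 of 6 myogenic and contractile genes. The genes were fbxo32, which encodes the muscle ubiquitin ligase atrogin-1 (miR-10 and miR-181a-5p), psmd5 (miR-143 and miR-143-3p), the kinase gene akt2 (miR-10c-5p) and the muscle glycogen phosphorylase gene pygmb (let-7-5p and let-7e). No site in akt2 was given for miR-10b-5p or miR-10b, and none in fbxo32 for miR-181a. The sequences of these names overlap those of miR-10c-5p and miR-181a-5p, so such a site depends on which overlapping name was used. The deposited predictions for miR-10 (684 transcripts) and let-7e (1585) had the same number of transcripts in each library although the sequence listed under each name differed, so their targets cannot be tied to the sequence read in each. The predictions carry no measurement of these genes.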

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

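The main scaling by library totals was chosen after the data were seen, in place of the sum over all names, which had been fixed beforehand and is given here as an alternative. The identical-sequence names, the sequence groups and the other denominators of the miR-10b-5p share were also chosen after the data were seen, and the remaining alternatives were planned. The count of 152 higher names became 234 with miR-10b-5p out of the totals, 284 with a minimum of 10 reads, 71 with 200, 333 with none, 95 at a ratio of 4 and 51 among identical-sequence names. The count of 218 lower names became 350 with a minimum of 10 reads, 391 with none and 76 among identical-sequence names. Counts under the remaining alternatives stayed within 1.5 times. The lower counts at stricter limits or in fewer names, and the higher counts at looser ones, follow from how those alternatives are built. Of 370 names meeting the size rule, 323 kept their side with miR-10b-5p out of the totals, 329 with the sum over all names, 346 with median centring and 351 with TMM. The list of miR-10, miR-99, miR-100 and miR-125 lay outside the random lists with other pseudocounts, read minimums or the more abundant arm only. Scalings move all ratios alike and so cannot change its percentile. Among identical-sequence names 2 lists lay outside (this one and the myomiRs) and among sequence groups 0 did; the cause was not tested. Its median turned to -0.037 with the sum over all names. In sequence groups the ratio of miR-10 turned to 0.87, those of miR-1956-3p and miR-2885 to -1.28 that of miR-4175-3p to -1.17 and that of miR-16 to -0.33, because the group counts sequences listed under other names. The share of miR-10b-5p was 21.3% (fed) and 26.5% (fasted) of the sum over all names and 56.2% and 71.8% of the sum over sequence groups. The median of 722 target transcripts became 55 (fed) and 57.5 (fasted) when only the sites of lowest energy were kept (at most -24.8 and -24.7 kcal per mol), since fewer sites were counted. Of 574 recomputed ratios of the 82 named miRNAs, 318 stayed inside their counting interval and 41 had the other sign, 22 of these with miR-10b-5p out of the totals. Of 121 recomputed list medians, 97 stayed inside their interval and 16 had the other sign, 8 of these with miR-10b-5p out of the totals and 3 with the sum over all names. Known miRNAs only left the values as they were, since no unnamed candidates were listed, and the authors' RPM carry the main scaling and gave 152 and 218. Variant shares were not run, since each name has 1 sequence per library. No paired analysis was possible because each group had 1 library.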

Other observations

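Several miRNAs outside the naming rule, chosen after their values were seen, gave ratios on identical sequences. miR-146b, a miRNA known from innate immune signalling, stood at 1221 RPM in the fed and 3013 in the fasted library (2.47-fold higher, 2.42 to 2.52), and miR-184 was 2.12-fold higher (2.08 to 2.17). miR-183-5p was 2.65-fold higher (2.21 to 3.19), miR-31-5p was higher by 1.15 on the log2 scale, miR-29a-3p was 2.27-fold higher (1.71 to 3.02) and miR-29c-3p 2.33-fold (1.77 to 3.11). miR-29a-3p and miR-29c-3p share a sequence group of 81 and 178 reads (log2 1.06). miR-215 was 3.51-fold lower (3.34 to 3.68) but shares a sequence group with miR-192 that had a log2 ratio of -1.52, and miR-486-5p, a miRNA abundant in muscle and red cells, was 3.14-fold lower (2.54 to 3.90). miR-30c-5p, whose sequence group includes miR-30b, was 2.25-fold lower (2.14 to 2.36) and miR-27c-5p 2.17-fold (2.07 to 2.27). These sizes depend on the scaling. With the sum over all names as the total, none of the higher names of this paragraph kept a ratio of 2. With miR-10b-5p out of the totals, only miR-215 of the lower names did.

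Among the muscle miRNAs the passenger arm miR-133a-5p was 2.54-fold lower (2.31 to 2.81) and miR-499a-5p, encoded in a slow myosin gene, 2.13-fold lower (1.67 to 2.73), while miR-206-3p had a ratio of 1.80 (1.57 to 2.08). miR-1a-3p, the most abundant miRNA of muscle in many species, had 2121 and 2305 reads, against 162374 and 109621 for miR-133a-3p. Its ratio was 1.04 (0.979 to 1.10) under the main scaling. With miR-10b-5p out of the totals every log2 ratio moved by 0.71, and with the sum over all names by -0.56. Both shifts exceed this interval, in opposite directions, so the direction of miR-1a-3p was not settled. The muscle names of this paragraph were also chosen after their values were seen. With miR-10b-5p out of the totals, neither miR-133a-5p nor miR-499a-5p kept a ratio of 2.

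Of the tests of patterns below, all but the one on sequence groups were chosen after the result was seen, and fasting itself was not tested, since each condition is 1 library. Names whose sequences differed between the libraries held larger ratios: 86.0% of 50 such names met the size rule, against 33.0% of identical-sequence names. Counting error was not tested apart from this: 5 of the 50 had an interval that held 1, but the size rule itself requires an interval that excludes 1. Listing of the sequence under another name at a like level stays open: 14 of the 50 had a sequence group with an absolute log2 ratio of at most 1, and the median of 5.95 excludes nothing, since each list gives 1 sequence per name and an unlisted sequence counts as 0. Such a name may stand for different RNAs in the 2 libraries, so that its ratio compares unlike sequences.

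A total of 159 names with at least 50 reads were read in 1 library alone. Their sequences had a median length of 20 bases and 28.3% were 21 to 23 bases long, against 22 bases and 72.4% for 352 identical-sequence names with at least 50 reads in both libraries. Their median GC content was 52.6%, against 45.5%. Many may therefore be fragments of RNAs other than miRNA. The tRNA A-box consensus was in 1 of the 159 and 5 of the 352. A fragment need not hold this motif, so its rarity does not weigh against fragments. Sequences of other RNAs such as rRNA were not searched. The same RNA under another name had a near match (16 bases, at most 1 mismatch) in the other library for 27 names (17.0%), and stays open for the rest because each list gives 1 sequence per name.

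miR-10b-5p took a larger share of the fasted library while the median name was lower. The 428 names outside the miR-10 family with at least 50 reads in both libraries had a median log2 ratio of -0.22 (quartiles -0.81 to 0.35), and with miR-10b-5p out of both totals 0.49 (quartiles -0.10 to 1.07). Fewer unlisted reads in the fasted library would move every listed name alike. As the whole cause they are argued against by an upper quartile below the 0.87 of miR-10b-5p. That bound was set after the values were seen, and the lower median of the other names is part of the pattern itself. A part of such reads in the difference stays open, since the unlisted share was not measured. Whether miR-10b-5p took reads from every other name cannot be told apart from a change in the other names, as the quartiles without it include 0. A difference caused by fasting may also account for the share, and was not tested.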
